A study of Equus caballus with 32 samples.

How the data were processed

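Bulk RNA sequencing of synovium, the membrane that lines a joint, was analysed in 32 libraries from 16 horses. Per the labels, 8 horses belonged to a control arm and 8 to an arm given iPAAG, a polyacrylamide hydrogel injected into the joint, and each horse code has a library at week 0 and a library at week 10. Per the labels' protocols, osteoarthritis was induced by making a bone and cartilage fragment in a middle carpal joint. The week 0 biopsy was taken by arthroscopy before the fragment was made and the week 10 biopsy after death. The tissue was digested with collagenase, the recovered cells were lysed, and libraries were made with a poly(A) selection kit. The labels do not say from which joint of a horse each library came.

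The deposited table holds whole-number counts per gene, which were not normalized as far as the values show. Per the submitters' processing notes, STAR 2.7.10b, limma 3.62.2 and the genome build EquCab3.0 were used, without a statement of what each did. The counting tool, the annotation release and the strand setting are not given in the sources used here, so genes that overlap or share near-identical copies are uncertain. The table lists 19418 Ensembl horse gene IDs, of which 0 were at zero in all libraries. Its name speaks of no zeros, so genes without counts appear to have been removed before deposit. The setting called no filter below starts from these IDs. In 6 genes, the 33 highest values of the table are written with 3 significant digits, so their last digits are lost. No 2 libraries held identical values. Every column was matched to a horse and week by its name.

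Total counts per library ranged from 5428928 to 56476566. Their precision differs accordingly, and the model weighs each count by its library total. Tests were made with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test, TMM factors, its filter for low counts by group and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05 on the adjusted p. Changes over time were fitted over all 32 libraries with the horse as a block and a separate week 10 term for each arm. This gave the change in the control arm, the change in the iPAAG arm, their mean with equal weight, and their difference, which is the test of the treatment. The arms were also compared within week 10 and within week 0 over 16 libraries each, without a block since the horses differ. A log2 fold change is given with its standard error, the absolute log2 fold change divided by the square root of the F statistic. Levels are given as CPM, the deposited counts scaled by library total and TMM factor. All p-values are two-sided.

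The horse was the block because the series is described as longitudinal and the same animal code appears at both weeks in the titles. The pairing rests on those codes. In the counts, the correlation between the deviations of the 2 libraries of a horse from their group means had a median of 0.0871 and ranged from -0.252 to 0.390. It was over 0.1 in 8 of 16 horses, and 6 of 16 week 0 libraries correlated best with the week 10 library of their own code among the 8 of their arm.

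The rule for named genes, the comparisons, the designs and most of the other settings were fixed before the data were examined. The rule took, per comparison, genes with a symbol that passed the threshold, had a mean log2 CPM of at least 2 and moved the same way in nearly all horses, ranked by log2 fold change. The table does not pair IDs with symbols. The reference table used for names has 39335 genes of another assembly and holds 0 Ensembl IDs, so 0 IDs could be given a symbol. The 49 planned gene lists, the gene set tests and the fixed genes of interest were therefore not run. In a departure made once this was known, the rule was applied without its demand for a symbol to the mean of both arms, with the same direction in at least 13 of 16 horses, and only the 2 IDs with the largest rise and the 2 with the largest fall are printed. No change is assigned to a pathway or cell type.

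The tests were tried on simulated counts drawn from the means and library totals of these libraries, with 200 genes changed by known folds. The changed genes were drawn from those with a mean log2 CPM of at least 2, so recovery of lower genes was not measured. Each horse had 1 mean over its libraries, so a library unlike the other of its horse was not reproduced. For the mean of both arms over 15184 genes, 23.9% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For the difference of changes over 15174 genes, these shares were 1.49%, 11.9% and 59.1%. For the arms at week 10 over 14301 genes they were 8.96%, 28.8% and 75.8%, that is 6, 19 and 50 genes, beside 12 false calls. False calls numbered 6 for the mean of both arms and 1 for the difference of changes. Each horse kept its own mean, so unchanged genes could still differ between the arms at week 10.

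Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors within edgeR, library totals without TMM, no filter, a filter of 1 CPM in 8 libraries, robust estimation, no block, the horse as a random effect, each arm alone, and leaving out each horse in turn. Leaving out control horses 2 and 11 together and limma-voom with library quality weights were added after seeing the data. Measures per library and per horse were compared with exact permutation or sign-flip tests in Python 3.11.15 with scipy 1.17.1.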

Results

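The series measured polyadenylated RNA in equine synovium at the time osteoarthritis was induced and 10 weeks later, in horses randomized to a control arm or to iPAAG, a 2.5% polyacrylamide hydrogel placed in the joint. Each of the 4 groups of arm and week held 8 libraries. Total counts were 42204981 ± 10819851 in control horses at week 0 and 33709953 ± 15741874 at week 10 (SD, n = 8). They were 43565758 ± 5082534 and 40149798 ± 7710800 in iPAAG horses (SD, n = 8). Genes with at least 1 count numbered 16143 ± 321 at week 0 and 15428 ± 2353 at week 10 in control horses, against 16170 ± 412 and 16472 ± 578 in iPAAG horses (SD, n = 8). None of 15 exact permutation or sign-flip tests of total counts, genes detected and the share of the 10 highest genes, between weeks or arms, passed adjustment, with a lowest adjusted p of 0.831.

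The week 10 libraries of control horses 2 and 11 stood apart from the other 30. That of horse 2 had 5428928 counts and 12018 genes, and that of horse 11 had 28614860 counts and 11373 genes. They lay at 255 and 281 on the first principal component, which held 29.3% of the variance, while the next highest library lay at 25.4.

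**Figure D1:**
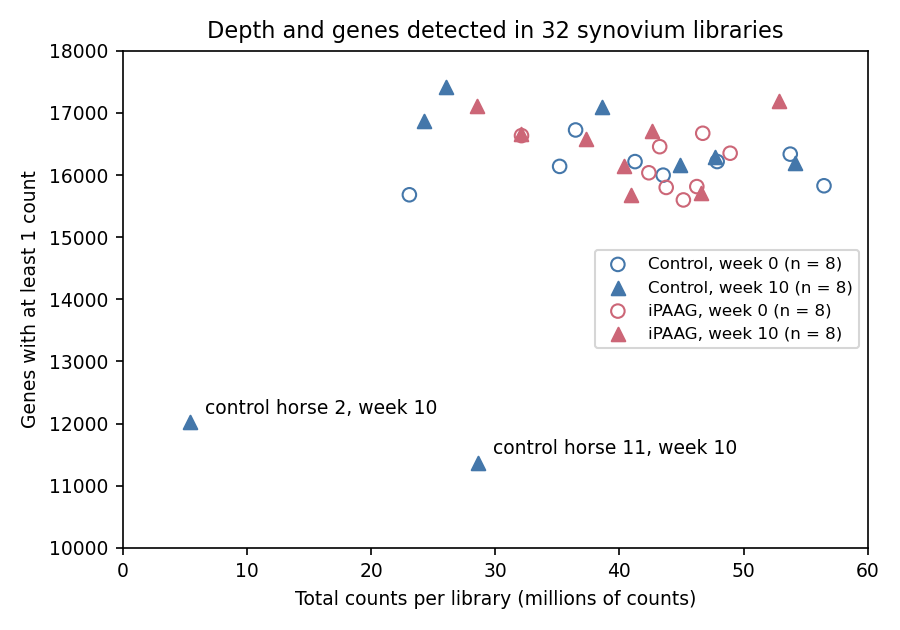
Total counts per library against the number of genes with at least 1 count, for 32 libraries, with open circles for week 0, triangles for week 10 and colours for the arms. The vertical axis does not start at 0, and the week 10 libraries of control horses 2 and 11 lie at 12018 and 11373 genes.

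The first question was how synovium changed over 10 weeks, in the mean of both arms. Of 15498 genes tested, 1298 rose and 1578 fell, 2876 in all. Rises outnumbered falls without the block (1850 and 1686), without control horse 2 (1603 and 1449), without control horses 2 and 11 (2169 and 2141), without horse 5 (1123 and 1105) and with library quality weights (3026 and 2923). Of the 2876 genes, 555 rose and 540 fell at least 2-fold, and 87 rose and 166 fell at least 4-fold. The median size of the log2 fold change among the 2876 was 0.80. The comparison holds together the passage of time, the induced osteoarthritis and the change from arthroscopic to postmortem collection. It also holds iPAAG in 8 of the 16 horses. The design does not separate these, and the labels do not say whether a library came from the joint with the fragment.

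The files do not pair the Ensembl IDs with gene names, so 4 IDs are given by their identifiers alone. ENSECAG00000013336 fell from 170 ± 87.7 to 6.92 ± 8.97 CPM in control horses and from 169 ± 91.6 to 23.5 ± 24.9 CPM in iPAAG horses (SD, n = 8). Its mean log2 fold change was -4.55 (SE 0.55, edgeR adjusted p = 2.72e-05), and it was lower at week 10 in 16 of 16 horses. ENSECAG00000055431 fell from 16.4 ± 18.9 to 0.913 ± 1.13 CPM in control horses and from 10.4 ± 7.33 to 0.795 ± 0.890 CPM in iPAAG horses (SD, n = 8). Its mean log2 fold change was -4.70 (SE 0.68, edgeR adjusted p = 0.00014), also lower in 16 of 16 horses.

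ENSECAG00000004158 rose from 2.19 ± 3.51 to 26.1 ± 15.2 CPM in control horses, and its level in iPAAG horses was 1.89 ± 2.40 CPM at week 0 and 16.3 ± 22.5 CPM at week 10 (SD, n = 8). Its mean log2 fold change was 3.32 (SE 0.70, edgeR adjusted p = 0.0029), and it was higher at week 10 in 15 of 16 horses. ENSECAG00000014484 rose from 2.07 ± 1.71 to 26.4 ± 14.4 CPM in iPAAG horses, and its level in control horses was 3.09 ± 4.15 CPM at week 0 and 8.99 ± 8.37 CPM at week 10 (SD, n = 8). Its mean log2 fold change was 3.01 (SE 0.57, edgeR adjusted p = 0.00129), and it was higher in 14 of 16 horses. It was lower in control horse 2 (11.5 to 5.65 CPM) and control horse 11 (7.64 to 3.66 CPM), whose week 10 libraries stood apart.

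**Figure D2:**
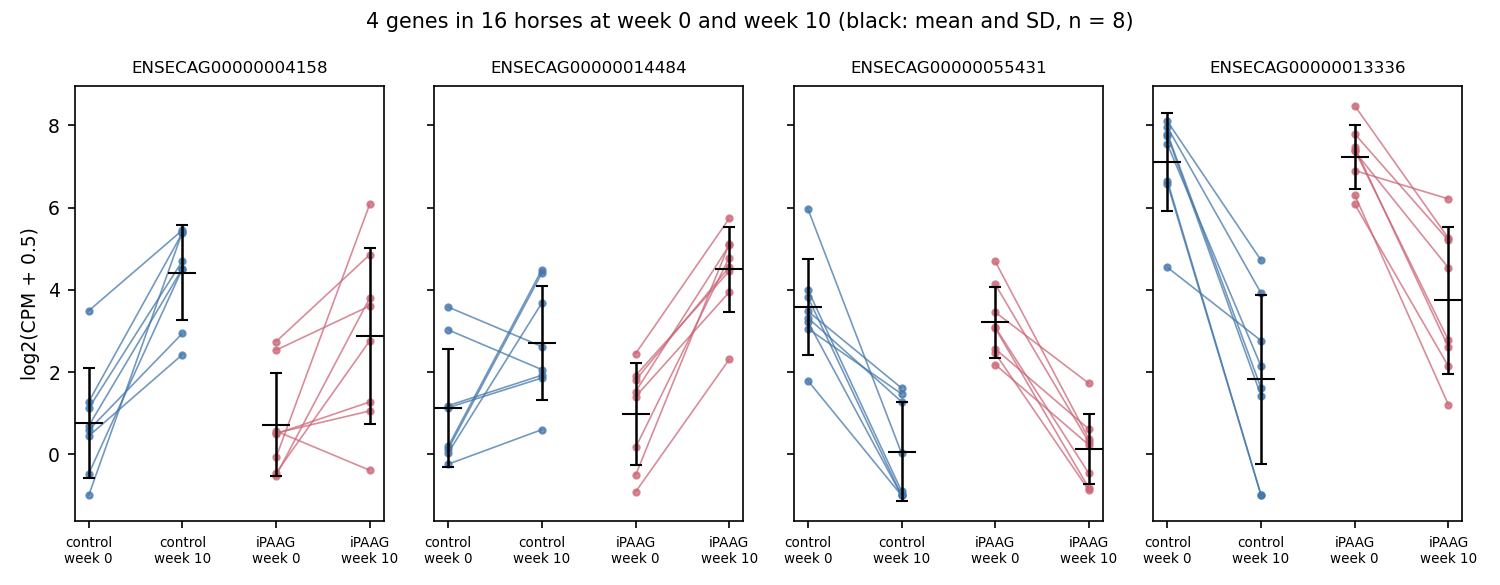
Level of 4 genes as log2(CPM + 0.5) in each horse at week 0 and week 10, with a line joining the libraries of a horse and black bars for the mean and SD of 8 horses. ENSECAG00000055431 and ENSECAG00000013336 were lower at week 10 in 16 of 16 horses, ENSECAG00000004158 higher in 15 and ENSECAG00000014484 higher in 14.

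In the control arm, 738 genes rose and 962 fell, 1700 in all, with a median log2 size of 1.15. Rises outnumbered falls with limma-voom (1046 and 1022), library quality weights (1395 and 1334), no block (1150 and 920) and the arm fitted alone (413 and 342). They also did so without horse 2 (838 and 669), without horse 5 (756 and 745) and without control horses 2 and 11 (1049 and 936). Of the 1700 genes, 485 rose and 506 fell at least 2-fold. ENSECAG00000013336 had a log2 fold change of -5.49 (SE 0.82, edgeR adjusted p = 0.000526) and ENSECAG00000055431 of -5.17 (SE 1.03, adjusted p = 0.0037). Both stood at 0 CPM in the week 10 libraries of control horses 2 and 11, and ENSECAG00000055431 also in that of control horse 15. Without control horses 2 and 11 the values were -4.67 and -4.32. Over the settings run, ENSECAG00000013336 ranged from -5.94 to -4.58, the latter with no block. ENSECAG00000055431 was -5.94 without horse 1, -5.91 without horse 13, -5.89 without horse 9, -4.55 without horse 10, -5.85 with DESeq2 and -4.09 with no block. ENSECAG00000004158 rose by 4.18 (SE 0.97, adjusted p = 0.00925). The value of ENSECAG00000014484 was 1.88 (SE 0.84, adjusted p = 0.176), which passed the threshold with DESeq2 (1.94, adjusted p = 0.01), with library quality weights (2.47, adjusted p = 0.0279) and without control horses 2 and 11 (2.99, adjusted p = 0.0219), over a range of adjusted p from 0.01 to 0.34. The count was 1017 without horse 15, 3209 with DESeq2 and 755 with the control arm fitted alone.

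In the iPAAG arm, 314 genes rose and 273 fell, 587 in all, with a median log2 size of 1.06. Falls outnumbered rises without control horses 2 and 11 (927 rose and 1005 fell). Of the 587 genes, 191 rose and 129 fell at least 2-fold. ENSECAG00000014484 rose by 4.14 (SE 0.78, edgeR adjusted p = 0.00731). ENSECAG00000055431 had a log2 fold change of -4.22 (SE 0.89, adjusted p = 0.0125; 0.0514 without horse 5) and ENSECAG00000013336 of -3.62 (SE 0.73, adjusted p = 0.0105). The value of ENSECAG00000004158 was 2.46 (SE 1.02, adjusted p = 0.207), and it passed the threshold with DESeq2 (2.50, adjusted p = 0.0101), limma-voom (2.87, adjusted p = 0.0367), library quality weights (3.10, adjusted p = 0.0044) and no block (3.11, adjusted p = 0.0481), over a range of adjusted p from 0.0044 to 0.431. The count moved from 212 without horse 5 to 1226 without horse 11 and also moved by over 1.5 times without horse 3, 6, 7, 12, 14 or 17. It was 1932 without control horses 2 and 11, 1786 with DESeq2 and 2393 with the iPAAG arm fitted alone. With library quality weights the count was 3855, with limma-voom 1257 and with the horse as a random effect 1274.

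The arms consist of different horses, so their changes share no library. Of the genes past the threshold in each arm, 391 were shared, 182 higher and 209 lower in both arms, where independent lists would share 15.0 and 16.9. Both lists come from 1 fit with a shared spread per gene, which can raise their overlap. With each arm fitted alone, over 14429 genes, 163 were higher and 225 lower in both arms. Independent lists would then share 34.6 and 27.4. Of the 1700 genes of the control arm, 96.7% had the same sign in the iPAAG arm, and of the 587 genes of the iPAAG arm 98.8% had the same sign in the control arm, against 73.0% of all 15498 genes. Without control horses 2 and 11, 986 genes were shared between 1985 and 1932. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.616 and Spearman's rho 0.606. Genes chosen on the control values had a median size of 1.15 there against 0.62 in the same direction in the iPAAG arm. Genes chosen on the iPAAG values had 1.06 there against 1.04 in the control arm. Without control horses 2 and 11 the pairs were 1.19 against 0.69 and 0.87 against 0.76. Choosing genes on the values of an arm raises their size in that arm, so these pairs are no test of a difference between the arms.

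**Figure D3:**
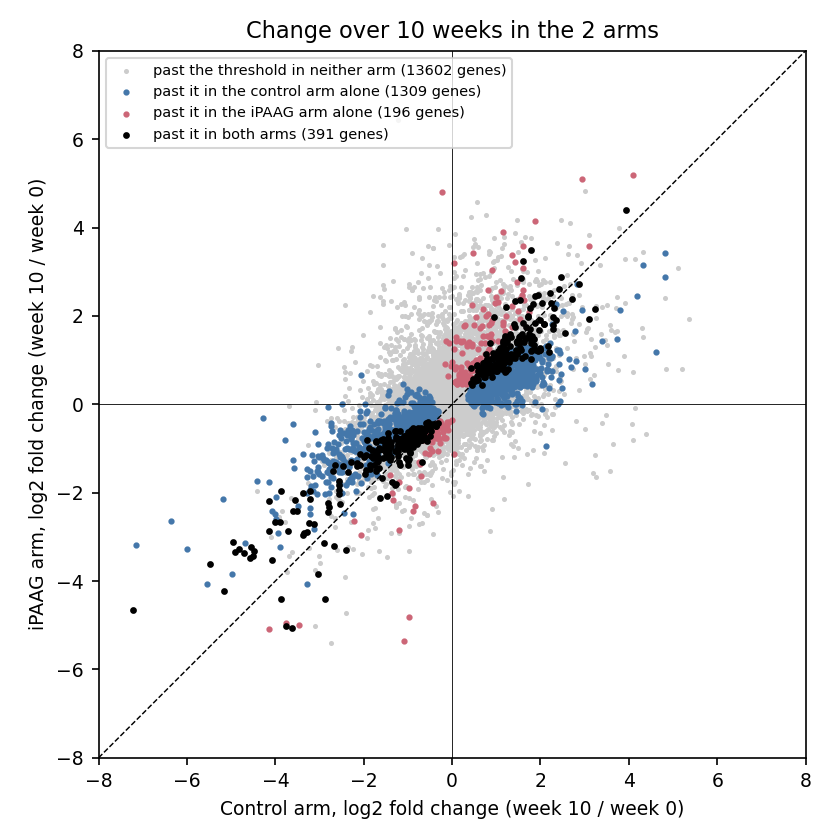
Log2 fold change from week 0 to week 10 in the control arm against that in the iPAAG arm, 1 point per gene over 15498 genes, coloured by the arm in which the gene passed the threshold. The 391 genes past it in both arms (black) have the same sign in both, and the dashed line marks equal change.

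The second question was whether the change over 10 weeks differed between iPAAG and control horses. The labels do not say when iPAAG was given or whether a library came from the joint with the fragment or from the other, so the time under treatment is not known here. In edgeR, 0 of 15498 genes differed in their change between the arms, with a smallest adjusted p of 0.496. At an unadjusted p under 0.05 there were 617 genes, 3.98%, and DESeq2 called 12. The 617 became 1003 without horse 9, 926 without horse 16, 402 without horse 3, 397 without horse 17, 1261 with library quality weights and 1300 with DESeq2. Without control horses 2 and 11 edgeR also called 0 genes, with 714 at an unadjusted p under 0.05. The difference of changes was -1.72 (SE 1.40) for ENSECAG00000004158 and 2.26 (SE 1.14) for ENSECAG00000014484 on the log2 scale, each with an edgeR adjusted p of 0.982. It was 0.95 (SE 1.35) for ENSECAG00000055431 and 1.87 (SE 1.02) for ENSECAG00000013336, also at 0.982. Over the settings run, the 4 values ranged, in this order, from -2.42 to -0.46, 1.09 to 2.78, 0.06 to 1.71 and 1.07 to 2.34. The 95% interval of the difference lay within 2-fold in either direction for 6030 genes, 38.9%, and within 4-fold for 10158 genes, 65.5%. Larger differences were not excluded for the rest. The count of genes past the threshold in each arm, 1700 and 587, is not a test of this difference.

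At week 10, 0 of 14654 genes differed between iPAAG and control horses in edgeR, with a smallest adjusted p of 0.0871. There were 1554 genes, 10.6%, at an unadjusted p under 0.05, from 1103 to 2075 when each horse was left out and 2469 in a model of all 4 groups without a block. DESeq2 called 98, the model of all 4 groups called 2, and leaving out horse 7 gave 1. None of the 4 IDs passed the threshold. The log2 value of iPAAG against control was 1.56 (SE 0.56, edgeR adjusted p = 0.358) for ENSECAG00000014484 and 1.74 (SE 0.94, adjusted p = 0.531) for ENSECAG00000013336. It was -0.68 (SE 0.77, adjusted p = 0.804) for ENSECAG00000004158 and -0.25 (SE 1.05, adjusted p = 0.962) for ENSECAG00000055431. The 95% interval lay within 2-fold for 6919 genes, 47.2%, and within 4-fold for 11901 genes, 81.2%.

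At week 0, before induction, the arms were compared as a check of the allocation. In edgeR, 0 of 14615 genes differed, with a smallest adjusted p of 0.794. There were 853 genes, 5.84%, at an unadjusted p under 0.05, and DESeq2 called 1. The 853 became 1902 without horse 7, 1312 without horse 13, 564 without horse 9, 1517 with library quality weights, 1343 with no filter and 201 in a model of all 4 groups without a block. The 4 IDs had values from -0.67 (SE 0.53) for ENSECAG00000055431 to -0.02 (SE 0.40) for ENSECAG00000013336. The 95% interval lay within 2-fold for 10917 genes, 74.7%.

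**Figure D4:**
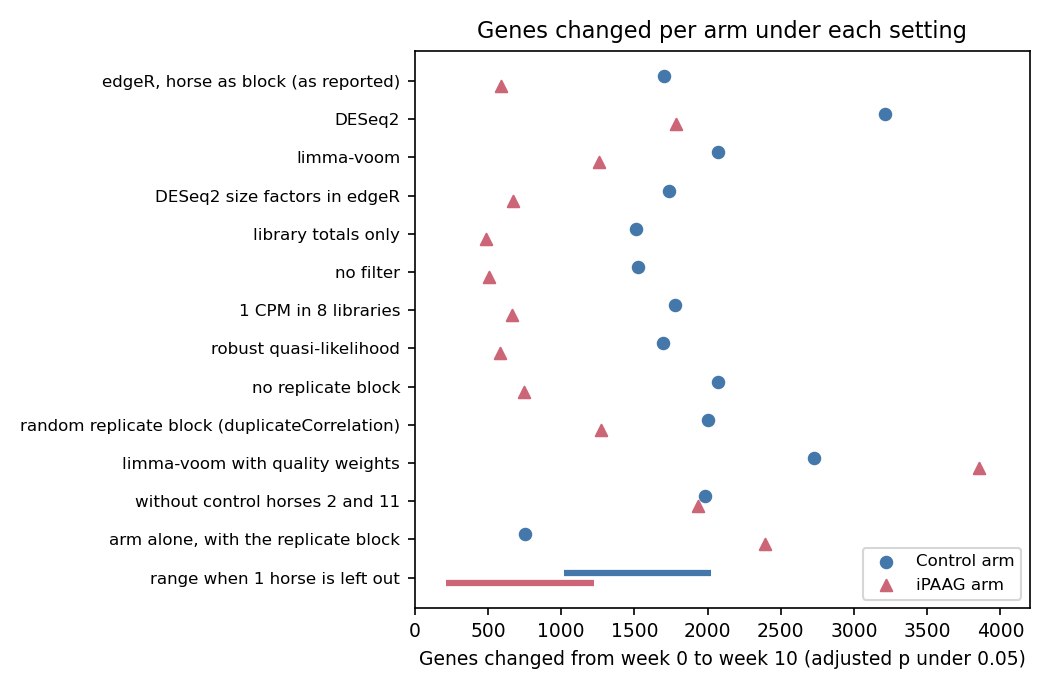
Number of genes changed from week 0 to week 10 in the control arm (circles) and the iPAAG arm (triangles) under each setting, with bars for the range when each of 16 horses is left out. The counts were 1700 and 587 as reported, 1985 and 1932 without control horses 2 and 11, and 755 and 2393 with each arm fitted alone.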

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

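In 30 groups of 8 values, the highest or lowest value was compared with the rest by the size of its gap. Chance marks about 1.5 such groups if values spread normally, and 5 were marked. A normal spread was not checked and CPM values were taken without logs, so 5 against 1.5 is no evidence of an excess. Where 2 values of a group lie far out together, as the genes detected in the week 10 libraries of control horses 2 and 11 do, each hides the other from this comparison.

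Total counts in the week 0 library of iPAAG horse 7 were 32117791, below the 42373584 to 48919206 of the other 7. ENSECAG00000004158 stood at 10.7 CPM in control horse 2 at week 0, against at most 1.92 CPM in the others of that group. The same gene stood at 67.1 CPM in iPAAG horse 5 at week 10, against 0.264 to 28.4 CPM. ENSECAG00000055431 stood at 62.3 CPM in control horse 16 at week 0, against 2.96 to 15.5 CPM, and at 2.81 CPM in iPAAG horse 7 at week 10, against 0.0440 to 1.03 CPM.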

How the results depend on the processing

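The settings without control horses 2 and 11 and with library quality weights were chosen after seeing the data. The sign of the log2 fold changes over time of the 4 IDs was the same under every setting run. These IDs were chosen from the same data for the largest mean changes among genes that moved the same way in nearly all horses. That choice makes a stable sign likely, so the sign is no test of how far the changes depend on the processing. The balance of rises and falls in each arm and in their mean was not the same under every setting, nor was the order of the arms by count. The count in the control arm, 1700, was 3209 with DESeq2, 2729 with quality weights and 755 with the arm alone, and ranged from 1017 to 2025 when each horse was left out. The count in the iPAAG arm, 587, was 1786 with DESeq2, 1257 with limma-voom, 1274 with the horse as a random block, 3855 with quality weights, 1932 without control horses 2 and 11 and 2393 with the arm alone, and ranged from 212 to 1226. The count in the mean of both arms, 2876, was 4526 with DESeq2 and 5949 with quality weights, ranged from 2228 to 3889, and was 4310 without control horses 2 and 11, of which 2724 were shared. The arm fitted alone uses fewer libraries and its own spread, and the cause of the other moves was not tested.

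Without the horse block, the counts were 2070, 749 and 3536 for the control arm, the iPAAG arm and their mean. The share of rising genes in the control arm was then 55.6% in place of 43.4%, and it was also over 50% without horse 2 (55.6%), with the arm alone (54.7%), without control horses 2 and 11 (52.8%), with quality weights (51.1%), with limma-voom (50.6%) and without horse 5 (50.4%). Without the block 1 gene differed in its change between arms. DESeq2 gave 12 genes for that difference, 98 between arms at week 10 and 1 at week 0. The model of all 4 groups without a block gave 2 at week 10. When each horse was left out, the difference of changes stayed at 0, the week 10 count was 0 to 1 and the week 0 count 0. The block changed no other count by over 1.5 times. Scaling moved the median log2 fold change of all genes by less than 0.1. The gene set tests and the named genes that need symbols were not run. Genes with a mean log2 CPM of at least 2 were simulated with a 2-fold difference of changes, at the library totals and fitted spread of these libraries. Of them, 11.9% were recovered, and the share of this limit due to depth was not tested.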

Other observations

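The tests of few RNA molecules, of low depth in horse 11, of the spread from control horses 2 and 11, of the distances within groups, and of the horse codes at later thresholds or with components removed were chosen only after the results were seen. The others were written before.

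The week 10 libraries of control horses 2 and 11 detected 12018 and 11373 genes. The other 6 week 10 control libraries, thinned to the same totals where deeper, detected 14987 to 16254 and 16008 to 17410, so these libraries lay 6.74 and 8.71 SDs below their means, which argues against low depth. Of genes expected at 80 to 320 counts, 3.48% had no count in horse 2 and 33.3% in horse 11, against at most 0.585% in the other 14 week 10 libraries, so few RNA molecules in the library may be a source, although loss of some cell types would leave zeros too. RNA of another cell type or tissue stays open for horse 11, since genes over 10 times their level in every other library held 0.437% of its counts against at most 0.144% elsewhere. No explanation by the arm or the week was tested for these 2 libraries.

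More genes passed the threshold over time in the control arm than in the iPAAG arm, 1700 against 587. Chance allocation of horses is not excluded: among 40 allocations to arms, the real one included, 6 gave a difference in counts as large as 1113, and the highest other was 1547. The ratio of the counts was 2.90 with all horses and 1.03 without control horses 2 and 11, so a pooled spread set by these 2 horses may account for it. Fitted alone, the order turned, with 755 and 2393 genes. An effect of iPAAG stays open, and the test of the difference itself called 0 genes.

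For the change over time shared by the arms, all 16 horses scored above 0 on the signature of the other 15 (500 genes that rose and 500 that fell most steadily). Scores ran from 0.57 to 1.75 on the log2 scale, which argues against week labels exchanged within a horse. Among the 7 horses with the deeper week 10 library the lowest score was also 0.57, which argues against depth as the only source. Depth hardly differed in 2 of them, horses 6 and 14 (ratios of week 10 to week 0 of 1.007 and 1.005). Horse 9, at a ratio of 1.94, scored 0.58. The mean score was 1.00 in the 7 horses and 1.14 in the rest, and a part due to depth was not tested. Whether horse codes mark the same animal was to be tested on genes on in some horses and off in others, but the planned thresholds left 1 gene, too few to decide. Of 4 threshold pairs tried after that, 1 left 8 genes, also too few, and the others left 29, 40 and 84 genes, at which 9, 7 and 6 of 16 week 0 libraries matched the week 10 library of their own code better than any other, and 10, 10 and 7 with ties counted. How ties count was not fixed beforehand, and it decides whether 2 of these pairs reach 10, the number set for holding the codes to be right. The number set against them was 5 or fewer. No rate of chance matches was computed for either number. Random matching to 1 of 16 libraries would give few best matches, so 5 or fewer could still exceed chance. For the 16 codes as a set the question stays open, and the block assumes that the codes hold.

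In those 3 comparisons the week 10 library of the own code ranked 11 or lower among 16 for control horses 1, 2, 11 and 15. For every other horse it ranked 8 or better, and for horses 9, 12, 13, 14, 16 and 17 it ranked 1 each time, ties included. The doubt from these ranks thus lies with control horses 1, 2, 11 and 15. Correlations of deviations from group means were also tried with 0, 3, 6, 8 and 10 leading components removed, and 2 to 4 of 16 week 0 libraries correlated best with their own code among all 16.

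Splits of the libraries bear on chance. Of 40 splits that exchanged weeks within horses, the real one included, 1 reached 1700 genes in the control arm (highest other 431). Also 1 reached 587 in the iPAAG arm (highest other 0) and 1 reached 2876 in their mean (highest other 0). Chance is therefore unlikely for these counts but not excluded, since 40 splits cannot show a share under 1 in 40. The splits also take the horse codes as right, and exchanging weeks adds the real change to the spread, which lowers the other counts. Between the arms the real counts were 0, which every allocation reaches by construction, so these splits decide nothing: 40 of 40 for the difference of changes (highest other 0), 100 of 100 at week 10 (highest other 0) and 100 of 100 at week 0 (highest other 1). The 1554 genes at an unadjusted p under 0.05 at week 10 were reached in 5 of 100 allocations, the real one included. The highest other count was 3062 and the median of the others 351. This share lies on the limit set beforehand, so chance is not excluded.

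The score on the shared signature was 1.23 ± 0.33 in control and 0.93 ± 0.31 in iPAAG horses (SD, n = 8, two-sided exact permutation p = 0.0796), and the exact p was 0.292 without control horses 2 and 11. The root mean square log2 distance of a library to the mean of the others of its group rose in the control arm from 0.489 to 0.911, higher in 7 of 8 horses (exact sign-flip p = 0.0156, adjusted over 6 tests 0.0469). Without control horses 2 and 11 it was 0.504 and 0.583, higher in 4 of 6 horses (exact p = 0.375), so the rise rests on these 2 horses. It was 0.466 and 0.485 in the iPAAG arm (exact p = 0.688). Over both arms it was 0.477 and 0.698, higher in 11 of 16 horses (permutation by sign flips, p = 0.0117, adjusted 0.0469), and without control horses 2 and 11 the exact p was 0.309. Each library also enters the mean against which the others of its group are measured, so these distances are not independent. The sign-flip p-values take them as independent and are only approximate. The iPAAG test is among the 6 under both sets of horses.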
